A study of Rhodotorula toruloides with 2 samples.

How the data were processed

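Total RNA from 1 chemostat sample per medium was used to make NlaIII tag libraries with Illumina's tag profiling kit, per the labels' protocols. In the usual form of this method cDNA is cut at CATG, another enzyme (MmeI) cuts a fixed distance downstream, and the resulting tag is joined to an adapter and sequenced, so that tag counts do not grow with transcript length. The tags listed here are 21 bases long. Steady-state cells were collected by centrifugation and frozen, per the labels' protocols. The aligner, the mismatch allowance, the treatment of tags matching several genes, the filters and the genome build are not given in the sources used here.

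The authors deposited 5 tables. Each library has a tag table with the count of each tag and a gene table with the count of tags per gene, and a further table sets both libraries side by side. The deposited counts are whole numbers without normalization. The deposited TPM values are tags per 1000000 tags, not scaled by length: each count divided by its TPM gives 1 constant per column. The authors' deposited log2 ratio divides these TPM values, with 0.01 in place of 0, and the deposited p-value and FDR come from a test that is not named in the sources used here. All columns of per-sample values were mapped to a library by name.

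The tables treat rare tags differently. The nitrogen-limited tag table lists 70555 tags seen once, of which 59181 are absent from the nitrogen-rich library. The nitrogen-rich table lists 10534 tags seen once, each also present in the nitrogen-limited library. The listed nitrogen-rich tags are 98.97% of the total behind their TPM values. In the joint table both libraries were filtered alike: leaving out tags seen once over both libraries gives 3454492 and 3600632 tags, the totals that its TPM values are scaled to. The counts of this joint table were therefore used as the gene counts. The nitrogen-limited gene table has 2013697 gene tags on 7123 genes against 2000070 in the joint table, and its use together with the nitrogen-rich gene table was tried as an alternative.

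The ratio of a gene or tag between libraries was computed from the counts after dividing by the library's gene tags (for tags, by all filtered tags). Its 95% interval is the exact conditional (Clopper-Pearson) interval of the ratio of 2 Poisson counts. A gene with at least 20 tags over both libraries was called higher or lower where the whole interval lay beyond 2-fold. TPM in the report are counts per 1000000 gene tags of a library unless credited to the authors. With 1 library per medium no gene was called by a p-value; an exact two-sided binomial test of the counts of each gene was used only to set beside the authors' deposited p-values, and the intervals compare these libraries, not the media in general. The assay has no molecular identifiers, so intervals cover counting error of reads only. Where a gene had 0 tags in a library, only the bound of the interval nearer to 0 was used. Shares of tags have exact binomial intervals. For tag ratios shown as medians, 0.5 was added to each count.

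The ratio, its interval, the minimum, the thresholds and scaling to library totals were set before the data were examined. So were 27 gene lists defined by words in product names, and a rule for the genes named. The rule took the 10 highest and 10 lowest by the end of the interval nearer to 0. It also took members of the lists, and the 5 genes with the most tags in each library. The reference table (assembly RHOziaDV1.0) matched all 7045 locus tags but pairs 0 of its 8171 genes with a symbol other than the locus tag, so 0 genes matched any list, no list was tested, and the condition on product names in the rule could not be applied. The rule was kept and only 2 locus tags per direction are printed, with the other genes it picks described as groups. The genome sequence was not used here, so planned counts of sense and antisense tags, of tag sites within genes, and recounts from tags were not made. The reference table was used only to match locus tags and to find which genes are neighbours, taken as consecutive locus tags between which the start position does not go back.

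Terminal A runs (3 or more bases), the 2 library-specific endings and the last 2 bases were examined after the tag tables had been seen, as were the choice of the joint table, the thresholds applied to the authors' FDR and the abundance classes. A full-length partner of a tag with 5 or more terminal A was the single tag of at least 20 copies, with fewer than 2 terminal A and neither ending, that began with all 14 or more bases before the run. An ending was counted where a tag ended in at least 5 bases of it or held it whole. Only the count of tag starts found with both endings also accepted slightly shorter endings. Alternatives for the gene counts were other scalings (all filtered tags, edgeR's TMM, DESeq2's median of ratios, gene tags without the 10 most abundant genes, and, added later, all tags without A-ended tags and tags with an ending), no low-count filter, a minimum of 100 tags, a ratio of at least 2 with an interval excluding 1, an interval widened by an assumed coefficient of variation of 0.2, and thinning of the deeper library.

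The calculations were tested on simulated data drawn from the observed abundances. For genes these were Poisson counts around the same proportions in both libraries, except for the genes changed. They held no biological or preparation difference, so they check the calculation and cannot give the rate of false calls in these libraries. Of 5462 unchanged genes 0 were called, 88.3% of 94 genes changed 4-fold and 96.8% of 93 genes changed 8-fold were called in the right direction, and 95.5% of 5649 intervals held the true ratio. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Only scaling factors were taken from edgeR and DESeq2, and no test of theirs was run.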

Results

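Rhodotorula toruloides (Rhodosporidium toruloides in the study's title) is a basidiomycete yeast called oleaginous because it can store large amounts of lipid. Its strain NP11 was grown in continuous culture (a chemostat) in a nitrogen-rich and in a nitrogen-limited minimal medium, and the study asked how transcript levels differ when nitrogen is scarce. Both media held 25 g/L glucose. The nitrogen-rich medium held 5 g/L ammonium sulfate and the nitrogen-limited medium held 0.2 g/L, with 6.3 g/L potassium sulfate to replace the missing sulfate. The stated protocol gives 1 dilution rate, 0.085 per hour, for both media, at 30 °C and pH 5.6. RNA was profiled by counting 21-base tags, each made of the CATG site of the enzyme NlaIII and the 17 bases after it. There was 1 library per medium and no replicate, so every difference below is a difference between 2 libraries with no replicate check. Intervals are exact 95% intervals for counting error only.

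The nitrogen-rich library held 3454492 tags and the nitrogen-limited library 3600632, once tags seen a single time over both libraries were left out. Of these, 2314492 tags (67.0%, exact binomial interval 66.9 to 67.0) had been counted to genes in the nitrogen-rich library and 2000070 (55.5%, 55.5 to 55.6) in the nitrogen-limited library. The tags fell on 7045 genes, of which 6758 had tags in both libraries, 129 only in the nitrogen-rich and 158 only in the nitrogen-limited library. The files identify genes by locus tag alone and no gene or product name could be paired with them, so pathways are not described and no coordinates are given. The 2 genes at each end of the ranking are given by locus tag, and the others as groups.

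The comparison of gene counts between the 2 libraries showed genes that were higher and genes that were lower in the nitrogen-limited library over the whole range of abundance. Among 5657 genes with at least 20 tags over both libraries, 780 (13.8%) were higher in the nitrogen-limited library and 525 (9.28%) were lower, with the whole interval of the ratio beyond 2-fold. The higher genes took 6.79% of gene tags in the nitrogen-rich and 26.9% in the nitrogen-limited library. The lower genes took 22.8% and 6.61%. Large ratios were more often in the upward direction, counted with scaling to gene tags only. The interval lay beyond 8-fold for 75 higher and 23 lower genes, and beyond 16-fold for 24 higher and 2 lower genes. Tags ending in runs of A, described below, were mostly far higher in the nitrogen-limited library. Whether any of them were counted to these genes was not determined. The remaining 4352 genes had intervals that reached within 2-fold, and the median log2 ratio of all tested genes was 0.09, with quartiles at -0.72 and 0.96.

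These counts rest on scaling each library to its gene tags. With scaling to all tags, as in the authors' deposited table, 582 genes were higher and 776 lower, so that the share of higher genes among the calls was 42.9% in place of 59.8%. That scaling shifts the log2 ratio of every gene by -0.27, TMM scaling shifts it by -0.11 and the median of ratios by -0.10. TMM scaling gave 679 higher and 623 lower genes. With the interval widened by an assumed biological coefficient of variation of 0.2 per library, which no replicate measures, 477 genes were higher and 282 lower. A point ratio of at least 2 with an interval that excludes 1 gave 1343 higher and 1015 lower genes.

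**Figure D1:**
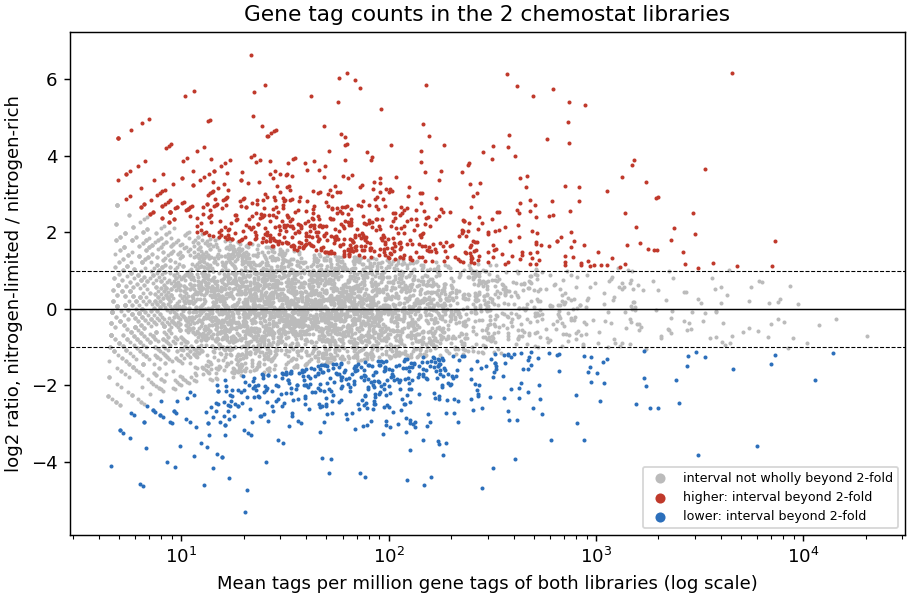
Each point is a gene with at least 20 tags over both libraries and tags in each, by the mean level of both libraries (x axis, log scale, tags per 1000000 gene tags) and the log2 ratio of the nitrogen-limited to the nitrogen-rich library (y axis, dashed lines at 2-fold). Red and blue points have the whole interval beyond 2-fold, and the 780 higher and 525 lower genes include 6 and 3 that had no tag in 1 library and are not drawn.

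**Figure D2:**
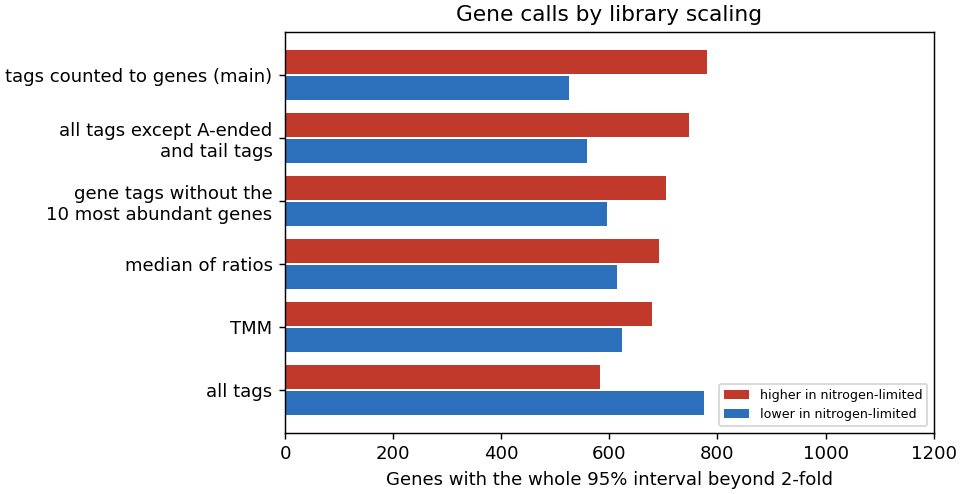
Bars give the number of genes higher (red) and lower (blue) in the nitrogen-limited library, with the whole 95% interval beyond 2-fold, for 6 ways of scaling the libraries. Higher genes outnumber lower genes in each of them except all tags, with 582 higher and 776 lower.

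The gene whose interval lay farthest above 2-fold, RHTO_02260, had 284 tags in the nitrogen-rich and 17808 in the nitrogen-limited library. Scaled to gene tags, it was 72.6-fold higher (95% interval 64.5 to 81.9), at 123 against 8904 TPM (here tags per 1000000 gene tags, without length scaling). RHTO_06380 went from 24 to 1464 tags and was 70.6-fold higher (47.3 to 110.5). At the other end, RHTO_04709 had 1256 tags in the nitrogen-rich and 42 in the nitrogen-limited library, and was 25.8-fold lower in the latter (19 to 36.0). RHTO_03551 went from 656 to 23 tags and was 24.6-fold lower (16.3 to 39.2). The 10 genes ranked highest by the end of the interval nearer to 0 each had an interval from at least 32.6-fold upward, and 2 of them had no tag in the nitrogen-rich library. The 10 ranked lowest were each lower by 11.4-fold or more over the whole interval. Which tags made up these gene counts was not determined. It is therefore not known whether tags ending in runs of A, described below, are part of the high ratios.

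Some genes had tags in a single library. Of those with at least 20 tags, 6 were seen only in the nitrogen-limited library, with 20 to 129 tags, and 3 only in the nitrogen-rich library, with 20 to 33 tags. The interval of the most abundant of the 6 started at 39.9-fold higher in the nitrogen-limited library. Most other genes with tags in a single library had counts too low for a ratio, with a median of 3 tags over all 287 such genes.

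Gene tags were concentrated in fewer genes in the nitrogen-rich library. Its 10 most abundant genes held 14.9% of gene tags, against 10.5% for the 10 most abundant of the nitrogen-limited library, and 4 genes were on both lists. A share of 50% of the gene tags came from 107 genes in the nitrogen-rich and from 142 in the nitrogen-limited library. All 10 of the most abundant genes of the nitrogen-rich library had ratios below 1, with log2 ratios from -3.59 to -0.26. Of these, 4 were lower in the nitrogen-limited library by more than 2-fold over the whole interval. These 10 were picked by their level in that library, which favours ratios below 1. The 5 most abundant genes of the nitrogen-rich library had 13740 to 25084 TPM there and log2 ratios from -1.88 to -0.26. The 5 most abundant of the nitrogen-limited library had 10179 to 15299 TPM and log2 ratios from -0.71 to 1.77. Among the 10 most abundant genes of the nitrogen-limited library, a pick that favours ratios above 1, 6 had such ratios. Of these 10 genes, 3 were called higher and 1 lower. When genes were classed by their mean over both libraries, which has no such preference, both directions were present in every class. Among 163 genes with a mean over 1000 TPM, 33 (20.2%) were higher and 24 (14.7%) lower. Among 1235 genes from 100 to 1000 TPM, 228 were higher and 184 lower. Among 3430 genes from 10 to 100 TPM, 464 were higher and 285 lower. Of the 829 genes under 10 TPM, 55 were higher and 32 lower, and the depth there limits what can be called.

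The authors' deposited table gives the same comparison as a log2 ratio for each gene. The log2 ratios in the authors' deposited table were within 0.05 of those recomputed on all tags for each of the 6758 genes with tags in both libraries. For the other 287 genes the authors' deposited table puts 0.01 in place of 0, which gives absolute log2 ratios of 5.81 or more to genes that mostly had only a few tags. With the thresholds of an FDR of at most 0.001 and a log2 ratio of at least 1 in size, set here, the authors' deposited table has 856 genes up and 1179 down.

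Tags were also compared without reference to genes. The most abundant tag in both libraries, CATGGGCTTCGGTCTCTTCGA, had 60314 copies in the nitrogen-rich and 43005 in the nitrogen-limited library. This is more than the largest gene count in either library, 58056 and 30598, so this tag had not been counted to a gene. Scaled to all tags it was 1.46-fold lower in the nitrogen-limited library (1.44 to 1.48). The tag CATGGGGATGTTGGCGAGGAG, with 58964 copies in the nitrogen-rich library, also exceeded every gene of that library and was 2.63-fold lower (2.59 to 2.67). A tag is named here by its sequence because no transcript sequence was used to assign it.

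Tags ending in 3 or more A made up 14.3% of the nitrogen-limited tags (14.2 to 14.3) and 0.59% of the nitrogen-rich tags (0.58 to 0.60). CATGGCCCCAAAAAAAAAAAA had 195 copies in the nitrogen-rich and 17704 in the nitrogen-limited library, 87.1-fold higher when scaled to all tags (75.6 to 100.8). The median log2 ratio was -0.31 for 6211 tags that do not end in A, 0.21 for 1275 tags ending in a single A, 3.95 for 122 tags ending in 3 A and 6.33 for 128 tags ending in 12 to 17 A.

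**Figure D3:**
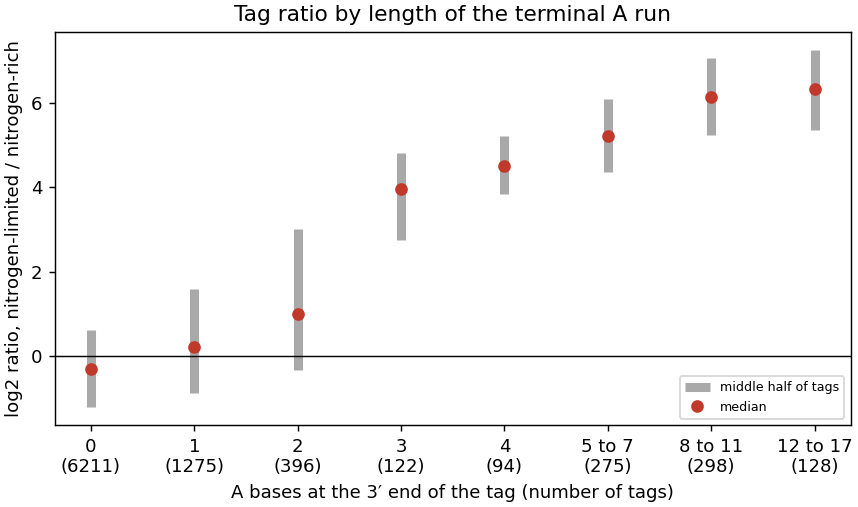
Tags with at least 50 copies over both libraries are grouped on the x axis by the number of A bases at the 3′ end, with the number of tags in brackets. The y axis is the log2 ratio of the nitrogen-limited to the nitrogen-rich library scaled to all tags (points, medians, and grey bars, interquartile ranges), and the median goes from -0.31 with no terminal A to 6.33 with 12 to 17.

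Other tags ended in a sequence found almost only in its own library. In the nitrogen-rich library 0.65% of tags ended in at least 5 bases of the sequence TGGACTACTG or held the whole of it, against 0.013% in the nitrogen-limited library. In the nitrogen-limited library 1.74% of tags ended likewise in TTAGATCAGG, against 0.033% in the nitrogen-rich library. The same tag start could carry either ending: CATGATCATCGTCCCCTGGAC had 8680 copies in the nitrogen-rich and 0 in the nitrogen-limited library, and CATGATCATCGTCCCCTTAGA had 0 and 20015. There were 17 starts that had at least 100 copies with each ending in its own library. This count also accepted endings slightly shorter than 5 bases and did not require absence from the other library. Once A-ended tags and tags with these endings were left out of the totals, the gene tags equalled 67.9% of the total in the nitrogen-rich and 66.1% in the nitrogen-limited library. Among all 14578 tags with at least 20 copies, 3252 were higher and 1949 lower in the nitrogen-limited library by more than 2-fold over the whole interval, scaled to all tags. Of the 12713 of them that were not A-ended and had neither ending, 1571 were higher and 1867 lower with that scaling, and 1906 were higher and 1431 lower when scaled to the total of such tags alone.

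The tag ratio also varied with the last 2 bases of the tag. Among 5237 tags with at least 100 copies, after leaving out A-ended tags and those with the endings above, the 303 tags ending in TT had a median log2 ratio of -2.48, and 87.1% of them were over 2-fold lower in the nitrogen-limited library, scaled to all tags. Tags ending in CC had a median of 0.75, and 2.10% of them were over 2-fold lower. Tags ending in AA had a median of 0.78. They have exactly 2 terminal A and were kept, so the shares of variance below include them. The last 2 bases accounted for 18.5% of the variance of the log2 ratio across tags, against 9.72% for bases 19 and 20, which hold 1 of them, and at most 2.13% for any pair of adjacent bases that held neither. Which of these tags were counted to which gene was not determined here, so the gene ratios above carry this dependence to an unknown extent.

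**Figure D4:**
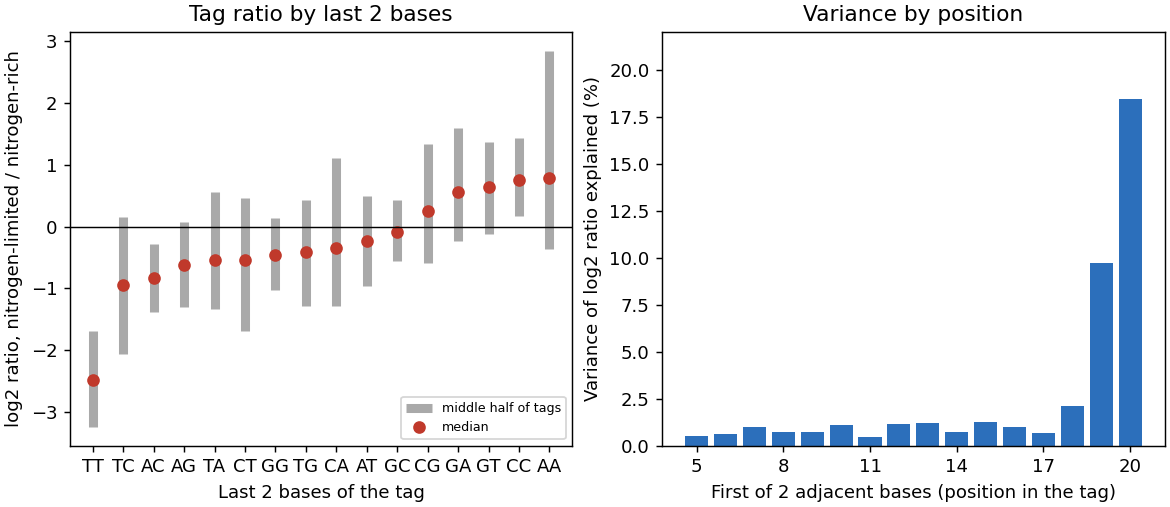
Left, log2 ratio of the nitrogen-limited to the nitrogen-rich library scaled to all tags, for tags grouped by their last 2 bases (points, medians, and grey bars, interquartile ranges), and right, the percentage of the variance of this ratio explained by each pair of adjacent bases, by the position of the first base. Tags ending in TT have a median of -2.48, and the last pair explains 18.5% of the variance.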

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

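The tests on A-ended tags and the totals without these tags were chosen after the results were seen. The shares of tags ending in 3 or more A and of tags counted to no gene were not part of the planned gene comparison. Each was larger in the nitrogen-limited than in the nitrogen-rich library, which serves as the control. The share of tags with the ending of the nitrogen-limited library was not planned either. Its larger value in that library follows from how the ending was picked. The ending of the nitrogen-rich library went the other way, with 0.65% of tags there and 0.013% in the nitrogen-limited library. Which A-ended tags, if any, were counted to genes was not determined.

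Tags ending in 3 or more A took 14.3% of the nitrogen-limited library and 0.59% of the nitrogen-rich library, and tags with the ending of the nitrogen-limited library took 1.74% and 0.033%. Of 275 tags with 5 or more terminal A, at least 50 copies and at least 14 bases before the run (CATG included), 145 had a single full-length partner of at least 20 copies that shared those bases, against 1 when the bases after CATG were shuffled. For these 145, a higher level of the transcripts as the whole reason is argued against: the 116 partners had a median log2 ratio of -0.17 (quartiles -1.33 and 0.79), the A-ended tags had a median of 5.23, and each of the 145 lay above its partner. For tags without such a partner this stays open. Different preparation or filtering of the libraries and a shift of transcript ends in nitrogen-limited cells cannot be told apart, since there was 1 library per medium.

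Tags counted to no gene made up 44.5% of the nitrogen-limited library and 33.0% of the nitrogen-rich library. Whether higher or lower genes were more numerous depended on the totals, and lower genes were in excess only with all tags in them. With only A-ended tags and tags with either ending left out of all tags, 747 genes were higher and 559 lower. The 10 most abundant genes as the whole reason are argued against. Leaving them out of the gene totals moved the share of higher genes among the calls by -5.62 percentage points, to 54.2%. A wider set of abundant genes was not tested. The 100 most abundant genes of each library held 49.0% of its gene tags in the nitrogen-rich and 43.7% in the nitrogen-limited library. With A-ended tags and tags with either ending left out of both totals, the share of higher genes among the calls was 57.2%. It was 42.9% with all tags and 59.8% with gene tags. The excess of lower genes with scaling to all tags may therefore come from A-ended tags and tags with an ending, as far as these match no gene, filling the nitrogen-limited total. A difference in the transcripts of the cells outside the annotated genes was not tested and stays open.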

How the results depend on the processing

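The per-library gene tables, the totals without A-ended tags and the other limits on A runs and their partners were chosen after seeing the data. Across the alternatives run, the number of higher genes ranged from 477 to 1343 and of lower genes from 282 to 1015. Counting each ratio of at least 2 with an interval that excludes 1 gave 1343 higher and 1015 lower genes. Widening the interval by an assumed coefficient of variation of 0.2 gave 477 and 282. In both cases the threshold itself is looser or stricter by construction. Lower genes outnumbered higher ones only with scaling to all filtered tags. The per-library gene tables gave 806 higher and 509 lower genes. No scaling shifted the genes by more than -0.27 (log2), too little to test the 4 genes given by locus tag. The share of A-ended nitrogen-limited tags was 11.1% with 5 or more A and 7.03% with 8 or more, since fewer tags meet the stricter definition. The partners of A-ended tags had a median log2 ratio of -0.26 with 10 or more shared bases and at least 1000 copies. Thinning the nitrogen-limited library to the nitrogen-rich total left 59546 of 60010 distinct tags. The recounts from tags and the alternatives for gene lists and for sense and antisense shares were not run. Gene sequences were not used here, and no names could be paired with the genes. No paired analysis was possible because each medium had 1 library. Depth limits genes under 10 TPM, of which 6.63% were higher and 3.86% lower, against 20.2% and 14.7% of genes over 1000 TPM.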

Other observations

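The tests of neighbouring genes, of the share of variance at the tag's end and of the deposited p-values were chosen after the results were seen. Neighbouring genes had slightly similar ratios. Across 4008 pairs of genes with consecutive locus tags, the rank correlation of log2 ratios was 0.062, above the highest of 10000 shuffles of gene order (0.057), and it was 0.014 for genes 2 places apart. It was 0.079 across 1679 pairs with at least 100 tags in each gene. There were 14 runs of at least 3 adjacent higher genes, against a mean of 6.93 and a highest count of 17 in shuffled orders. There were 4 runs of at least 3 lower genes, against a mean of 2.15 and a highest count of 8, so the runs alone lay within the shuffled range. The correlation is across genes of these 2 libraries, and genes are not independent replicates. That neighbouring genes changed together may be followed up as a hypothesis, and tags shared by overlapping transcripts were not tested as another reason.

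The dependence of the tag ratio on the last 2 bases is a candidate technical part of the difference between libraries. GC content of the last 2 bases is argued against as the whole cause. Among endings without G or C, median log2 ratios ran from -2.48 for TT (quartiles -3.24 and -1.69) to 0.78 for AA (-0.37 and 2.84). Tags ending in AA have 2 terminal A, so the rise with terminal A described above may be part of their ratio. Without AA, the other endings of this kind had medians of -0.24 for AT (quartiles -0.96 and 0.50) and -0.54 for TA (-1.33 and 0.56). The mean of each GC class of the other bases after the site was then removed, which took out 5.89% of the variance. Of the variance left, the last 2 bases accounted for 20.3%. That step leaves out GC content of the last 2 bases, so it cannot decide on GC content of the whole tag. Without that step the last 2 bases accounted for 18.5% of the whole variance (19.1% and 16.4% with at least 50 and 200 copies). The 20.3% is a share of the variance left, so the 2 values are not on the same scale. Bases 19 and 20, which hold 1 of them, accounted for 9.72%, and adjacent bases that hold neither for at most 2.13%. The highest of 1000 shuffles gave 0.741%. A difference in the joining of tags to adapters could give this pattern, since in the usual form of this method MmeI leaves the last bases as an overhang there. Other effects at the tag's end cannot be told apart from it here. Scaled to all tags, centring the tags of each ending on a common median took the tags over 2-fold lower from 1460 to 1258 and those over 2-fold higher from 1064 to 938. No biological explanation was tested.

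In the authors' deposited table, 168 genes had a p-value over 1e-15 although an exact two-sided binomial test of their counts, which compares the libraries only, gave a p under 1e-30. All 168 were higher in the nitrogen-limited library, out of 280 higher and 432 lower genes with such an exact p, and 0 of them had a deposited FDR above 0.001.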
